A study of Homo sapiens with 50 samples.

How the data were processed

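ATAC-seq (an assay in which a transposase inserts sequencing adapters into accessible chromatin) was applied to ASC52telo cells, an hTERT-immortalised line of human adipose-derived mesenchymal stem cells. There were 50 libraries in 13 groups. 1 group held 3 undifferentiated libraries of day 0, and the others held cells taken through adipogenic differentiation for 3, 7, 10 or 14 days with the DMSO vehicle, ROSI (rosiglitazone, an agonist of the fat cell nuclear receptor PPAR-gamma) or TBT (tributyltin, an organotin that binds PPAR-gamma and its partner RXR). Per the labels, differentiation used a commercial adipogenic supplement, the chemicals were added in DMSO at nanomolar doses that are not given in the sources used here, and libraries followed the Omni-ATAC protocol with changes for cells rich in lipid. Groups, days and replicate numbers were taken from the labels. The sample titles carry the same flow cell and lane code in every library, so no sequencing batch could be compared. Whether replicates came from separate cultures is not stated, so the p-values measure only the spread between these samples, which may be technical.

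Each library came as a list of peaks on the human hg38 build. Per the submitters' processing notes, the tools were Trim Galore 0.6.5, FastQC, BWA, SAMtools and MACS2; their settings and the treatment of transposase offsets are not given in the sources used here. The score that the authors deposited for each peak equalled 10 times the −log10 q-value, capped at 1000, for at least 99.98% of the peaks of every library. The fold enrichment that the authors deposited is a linear ratio of the peak over the caller's background. The authors' deposited −log10 p and −log10 q values are the caller's own, with no normalization between libraries. Another deposited column gives the summit position within the peak. These values belong to single peaks and were used only to rank or describe peaks within a list. Read totals were not used here, so the sequencing depth is unknown, and the number of peaks is the only measure of yield.

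The peak numbers in the lists run higher than the number of peaks kept (48.0 to 83.0 peaks per 100 numbers), and the list names point to a reproducibility filter. How the replicates entered that filter is not stated. Within a group a median of 97.8% to 98.9% of the peaks of a list overlapped the list of another replicate, against 81.6% to 84.7% between compounds of a day. The filter thus probably acted on a set of peaks shared by a group, so presence in replicates of 1 group may not be independent, and every p-value over libraries would then be too small. With 1 value per group, the 4 days of a compound comparison could give no exact p below 0.125.

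Because lists differed in length, every list was limited to chromosomes 1 to 22 and X, ranked by the authors' −log10 p and shortened to the top 36333 peaks, the length of the shortest list. Differences in peak number near a gene are therefore relative to the rest of the genome. Regions were 501 bp windows on peak summits without overlaps, kept if seen in at least 2 libraries, which gave 68379 regions, of which 13219 (19.3%) had a peak in every library. Peaks per gene were summits within 50 kb of the annotated span of each of 19970 protein-coding genes of GRCh38.p14, the same assembly as hg38. Genes with a mean of at least 1 peak were tested. The median gene window held 3.04 peaks. Neighbouring genes share windows, and a peak near a gene need not act on it.

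There were 26 gene lists with 637 entries for 610 genes, 27 of them in more than 1 list. They covered adipocyte lipid storage and secreted products, adipogenic transcription factors, inhibitors of adipogenesis, thermogenic genes, PPAR and RXR partner receptor targets, actin cytoskeleton and focal adhesion, microtubules with intermediate filaments and motors, SRF and YAP/TEAD targets, extracellular matrix, TGF-beta signalling, mesenchymal stem cell surface markers, osteogenic and chondrogenic genes, muscle, endothelial, blood cell, epithelial and neural markers, metal binding and metal response, the NRF2 oxidative stress response, heat shock and unfolded protein response, cell cycle, inflammatory and NF-kB targets, glucocorticoid and cAMP targets, insulin and IGF signalling, and housekeeping genes. A list's value in a library was the sum of the peaks near its genes. Random lists took, for each gene, another from the 201 nearest in the order of mean count.

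The 5 comparisons were differentiated DMSO against day 0, day 14 against day 3 with labels permuted within compound, and TBT against DMSO, ROSI against DMSO and TBT against ROSI with labels permuted within day. Each region, gene and list was tested by an exact stratified permutation test, two-sided, with Benjamini-Hochberg adjustment at 0.05 over the features of its kind. Peak totals per library used the same test, with 100000 permutations where there were more splits. Differences are averages over strata, with the standard error (SE) of that average. For single days, exact permutation tests were run on list sums, and regions with a peak in all libraries of a group and none of another were counted beside other splits. Similarity was the Jaccard index of region presence, tested one-sided over all partitions of a day's libraries.

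Genes named in the text are the 10 largest differences in each direction among called genes with the same sign in every stratum, taking the first of genes within 100 kb. Up to 3 members with the smallest p of every called list were added, and PPARG, CEBPA, ADIPOQ, FABP4, PLIN1, LPL, CD36, UCP1, RUNX2 and ACTA2 were always included. FABP4 lay below the minimum of 1 peak. A gene that the rule names is not reported here. For regions, 3 per comparison and direction were taken by smallest p, then difference and rank. Where other list members are named without values, they are the called members.

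The lists, tests, named-gene rule and most alternatives were chosen before the data were examined. The alternatives were all deposited peaks, the top 30000 peaks, labels permuted only within replicate numbers, each library left out, windows of 10 kb and 100 kb, no minimum count, limma on log2 counts with a pseudocount of 1, merged regions, cover of at least 251 bp of a window, every variable region, each peak counted once per list, peaks with a −log10 q of at least 5, and covered length. The top 10000 peaks and the omission of day 3 were added after the data were seen. Gene spans replaced annotated 5′ ends because the gene table used here gives no strand, and exon, intron and UTR positions were not used for the same reason. 18 planned motif shares were not computed because no genome sequence was used here.

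The calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The tests were tested on simulated data with 200 changed genes or regions. In TBT against DMSO, genes changed by 1 peak were recovered in 48% of cases and by 2 peaks in 99%. For ROSI against DMSO these shares were 56% and 94%, for TBT against ROSI 40% and 98%, and for day 14 against day 3 19% and 89%. The 3 day 0 libraries allow no p below 0.00123, so that comparison recovered 0 genes when 200 of 15247 were changed, and 17.1% and 70.3% when 4000 of 15421 were. None of 4000 changed regions was recovered there.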

Results

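Accessible chromatin was mapped by ATAC-seq in 50 libraries of ASC52telo cells, a human adipose-derived mesenchymal stem cell line, before and during adipogenic differentiation. The 3 undifferentiated libraries of day 0 carry the DMSO label as well. Differentiating cells were sampled at 4 days. DMSO had 3 libraries at day 3 and 4 at days 7, 10 and 14. ROSI had 4 libraries at days 3, 7 and 10 and 3 at day 14, and TBT had 5 at day 3 and 4 at the later days. The libraries held 36742 to 98123 peaks (median 67384.5, total 3275510) that covered 15.6 to 59.9 Mb, and the median fold enrichment of a peak ranged from 5.97 to 11.1. Read depth is unknown. Coordinates are on hg38. A peak inside a gene's span was not assigned to an exon, intron or UTR.

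Undifferentiated cells had the most peaks, 97365 ± 714 (SD, n = 3), and DMSO cells at day 3 the fewest, 41727 ± 939 (n = 3). At day 3, ROSI cells had 62866.5 ± 1062 peaks (n = 4) and TBT cells 49822 ± 7425 (n = 5). From day 7 on, the means of DMSO were 75409, 70601 and 67916 peaks, those of ROSI 67993, 58672 and 63866, and those of TBT 69843, 64200 and 66882. Differentiated DMSO libraries held fewer peaks than day 0 libraries (difference −31972, SE 3309, exact permutation test, two-sided, Benjamini-Hochberg adjusted p = 0.00613), and all 15 lay below all 3. Averaged over the compounds, peak numbers rose from day 3 to day 14 by 14749 (SE 1203; permutation test with 100000 resamples, two-sided, p = 6e-05, Benjamini-Hochberg adjusted p = 0.0003). The rise was 26189 (SE 706) in DMSO and 17060 (SE 3382) in TBT (exact permutation test, Benjamini-Hochberg adjusted p = 0.0476 for both), and ROSI differed by 999 (SE 1047, p = 0.343). Averaged over days, TBT differed from DMSO by −1226 peaks (SE 1215, permutation p = 0.426), ROSI from DMSO by −564 (SE 777, p = 0.633) and TBT from ROSI by −662 (SE 1248, p = 0.592). These averages hide opposite signs. ROSI minus DMSO was 21140 peaks at day 3 and −7417, −11929 and −4050 at days 7, 10 and 14, and TBT minus DMSO was 8095, −5567, −6401 and −1033.

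**Figure D1:**
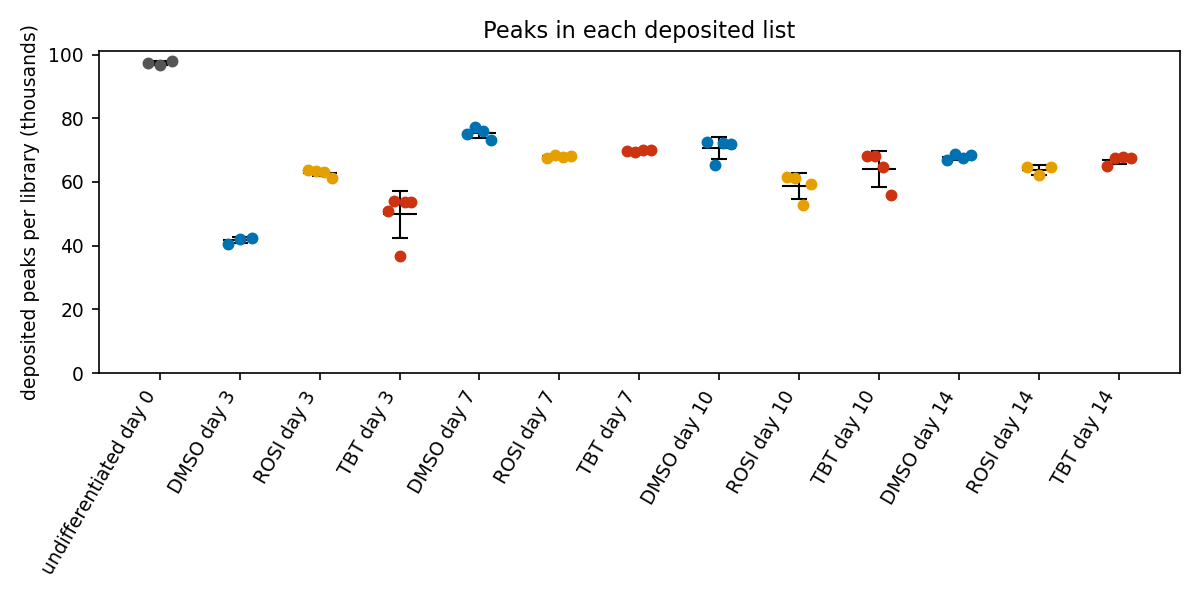
Peaks per library (vertical axis, unit 1000) for the 13 groups (horizontal axis); dots are libraries and bars show the group mean with its SD. The day 0 group lies highest at 97365 peaks and DMSO day 3 lowest at 41727.

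Libraries given the same compound were more alike than libraries of different compounds at every day. In lists shortened to the top 36333 peaks, the mean Jaccard index of region presence within groups was 0.808 at day 3, 0.806 at day 7, 0.782 at day 10 and 0.803 at day 14. Between compounds it was 0.697, 0.705, 0.698 and 0.678. The exact permutation p, one-sided, was 3.61e-05 at day 3 and 0.000173 at the other days, the smallest the numbers of partitions allow (Benjamini-Hochberg adjusted p = 0.000144 and 0.000173). By day 14 DMSO and ROSI libraries shared more regions (0.758) than TBT shared with DMSO (0.640) or with ROSI (0.648). At day 3 the order was another, with ROSI and DMSO the least alike (0.680), TBT and DMSO at 0.695 and TBT and ROSI at 0.7102. Replicates of a group probably share a reproducibility filter, so presence may not be independent between them. With 1 value per group, no compound comparison over the 4 days could reach an exact p below 0.125, which limits every test over libraries given here.

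The comparison of differentiated DMSO cells (n = 15) with day 0 (n = 3) addressed what differentiation in the vehicle changed. Peaks near genes of glucocorticoid response, insulin signalling and adipogenic transcription rose in lists of equal length, and those near epithelial, endothelial, muscle and microtubule genes fell. ZBTB20, a zinc finger repressor (chromosome 3, 114314500 to 115147288), rose from 6.0 ± 1.0 peaks (SD) to 18.1 ± 1.81. FBXL7, a subunit of a ubiquitin ligase, rose by 11 peaks from 3.0 ± 1.73. KCNMA1, a calcium-activated potassium channel (chromosome 10, 76869602 to 77637808), fell by 10.9 peaks to 9.07 ± 1.28.

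In total 4760 of 15993 genes were called, 2164 higher and 2596 lower (exact permutation test, two-sided, Benjamini-Hochberg adjustment; 45.5% higher). Of 33353 regions, 12254 were called, 5641 higher and 6613 lower. The other genes with the largest gains were ARHGAP26 (10.8 peaks more), SLIT3 (9.4), LRMDA (9.0), PRKG1 (8.8), PTPRG (8.47), KIF6 (8.33), RBMS3 (8.2) and PARD3 (7.93). The windows of ARHGAP26 also hold NR3C1, the glucocorticoid receptor gene. The other large losses were at ASAP1 (difference −7.53), CMIP (−7.47), CDH13 (−7.33), ZMIZ1 (−7.27), CNIH3 (−7.13), TGM2 (−6.53), TNC (−6.53), TAS2R1 (−6.47) and MAD1L1 (−6.4). All 20 had the smallest adjusted p this design gives (exact permutation test, Benjamini-Hochberg adjusted p = 0.00821).

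Of the 26 gene lists, 15 were called, 9 higher and 6 lower, with exact permutation tests and Benjamini-Hochberg adjusted p between 0.00455 and 0.0340. Glucocorticoid and cAMP targets rose by 15.8 ± 1.53 peaks (SE), with 7 members higher, 2 lower and 12 not called (8 higher and 4 lower when adjusted over the list alone). Among them were ZBTB16, a glucocorticoid-induced transcription factor (11.8 against 6.33), TSC22D3, which encodes GILZ (8.2 against 5.33), and FKBP5, a co-chaperone of the glucocorticoid receptor (4.67 against 2.0). Adipogenic transcription factors rose by 15.2 ± 3.11, with 6 higher, 4 lower and 14 not called (6 and 5 when adjusted over the list alone). PPARG, the master regulator of fat cell differentiation, had 6.8 ± 0.676 peaks against 3.67 ± 1.53, and EBF1 18.7 against 13.0, while EBF2 fell from 8.33 to 4.27. Insulin and IGF signalling rose by 13.6 ± 1.90 (4 higher, 2 lower, 16 not called), including PIK3CA and IGF1, which had 0 peaks at day 0 and 3.73 ± 1.10 afterwards. Mesenchymal stem cell surface markers rose from 99.7 ± 2.52 (SD) to 114.67 ± 5.58 peaks (5 higher, among them ANPEP, CD44 and NT5E, 1 lower, 14 not called). PPAR and RXR partner receptor targets rose by 10.1 ± 5.10 (6 higher, 2 lower, 19 not called), with PDK4, which restrains glucose oxidation, at 5.0 peaks in each DMSO library and 1.0 in each day 0 library. Inhibitors of adipogenesis (9.2 ± 2.64), NRF2 targets (8.67 ± 1.81), TGF-beta signalling (8.07 ± 1.90) and chondrogenic genes (5.8 ± 1.64) rose as well.

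Microtubule, intermediate filament and motor genes fell by 19.7 ± 2.34 peaks, with 10 lower, 4 higher and 18 not called (11 and 5 when adjusted over the list alone); TBCD, a tubulin chaperone, went from 12.3 to 7.4. Endothelial markers fell by 13.5 ± 2.47 (6 lower, 2 higher, 6 not called), although KDR, a VEGF receptor, rose from 0 to 2.27. Epithelial markers fell by 12.7 ± 1.72 (5 lower, 1 higher, 8 not called), with the neighbouring keratin genes KRT8 (8.33 to 2.6) and KRT18 (5.0 to 1.07). The extracellular matrix list fell by 11.6 ± 1.71 (9 lower, 6 higher, 18 not called), with TNC and COL4A2 lower and COL8A1 higher. Muscle markers fell by 10.7 ± 1.44 (0 higher, 3 lower, among them TTN, and 6 not called) and thermogenic genes by 6.47 ± 2.46 (5 lower, 3 higher, 10 not called). UCP1, the uncoupling protein of brown fat, had 1.0 peak in every DMSO library against 2.0 at day 0. ADIPOQ, the adiponectin gene, fell from 5.67 ± 0.577 to 3.0 ± 0.535, PLIN1 and CD36 each rose by 1.87 and RUNX2, an osteogenic factor, by 2.53. CEBPA, LPL and ACTA2 were not called (differences −1.07, 0.60 and 1.47). The lists not called were lipid storage (6.07), actin (5.8), SRF and YAP/TEAD targets (2.07), osteogenic genes (5.4), blood (−0.867) and neural markers (−2.4), metal response (−1.93), heat shock (6.6), cell cycle (−0.2), inflammatory targets (−2.2) and housekeeping genes (1.6).

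Each called list was set beside 6 other settings: the top 30000 peaks, a replicate block, windows of 10 kb and of 100 kb, each peak counted once, and any 1 library left out. Of the 15 calls for day 0, 4 held in all 6 of them (microtubule, endothelial, epithelial and glucocorticoid lists). The calls of thermogenic genes, PPAR targets and NRF2 targets were lost in 3, the NRF2 call with the block, with 100 kb and with a library left out. Those of extracellular matrix, TGF-beta and chondrogenic genes were lost in 2. The extracellular matrix call was lost with both window sizes, and its difference with 100 kb was 0.133. Lists were also set beside 10000 random lists of genes with like mean counts, a comparison chosen after the results were seen. Random genes were drawn separately, so lists with neighbouring genes that share peaks can stand further out for that reason alone. The microtubule (percentile 0.76), endothelial (0.91) and epithelial lists (2.03) lay outside the central 95% of these. The gains did not, with stem cell surface markers at 97.2, insulin genes at 96.8, glucocorticoid targets at 95.3, adipogenic factors at 89.9 and NRF2 targets at 87.2. TGF-beta signalling stood at 59.5, where random lists gained a median of 5.6 peaks, and thermogenic genes at 35.8.

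A region that overlaps VCPIP1 (chromosome 8, 66667136 to 66667636) and regions in PC, the pyruvate carboxylase gene, and in RAB1A had a peak in all 15 DMSO libraries and 0 of 3 day 0 libraries. The lower regions named by the rule were 3 neighbouring windows on chromosome 1 between 631771 and 634280, in a stretch of nuclear DNA that resembles the mitochondrial genome, which had a peak in 3 of 3 day 0 libraries and 0 of 15 (exact permutation test, Benjamini-Hochberg adjusted p = 0.00449). Whether reads in these windows came from that stretch or from the mitochondrial genome was not tested. Each of the named regions rests on 3 day 0 libraries. Without any 1 of them the exact permutation test called 0 regions (3325, 3551 and 3445 at an unadjusted p under 0.05 without replicates 1, 2 and 3). This 0 says little, since only regions with at least 3 libraries with a peak and 3 without were tested. With a day 0 library left out, that rule removed every complete difference, and the smallest p was 0.0221. No other tool was run on regions. Called genes numbered 2778, 3112 and 2933. With all deposited peaks, which are more numerous at day 0, 408 genes were higher and 10719 lower (3.67% higher). Of the calls made in both settings 695 changed direction. Of the gains near named genes only that of KDR stayed called in the same direction. PDK4 was not tested there because every library had the same count, so its gain was absent. Of the lists, 0 were called higher there and 24 lower, and every list that had gained had the opposite sign. With the top 10000 peaks the PPAR target list fell (−5.4), and the extracellular matrix (2.87) and endothelial lists (2.4) were not called and had the opposite sign.

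The comparison of day 14 with day 3 asked what changed while differentiation went on, within compounds. Peaks near glucocorticoid and cAMP targets and insulin and IGF genes rose in all 3 compounds. ZBTB16 (chromosome 11, 114059711 to 114256770) rose from 9.17 ± 1.40 peaks (SD, n = 12) to 13.7 ± 1.10 (n = 11), by 2.58 in DMSO, 3.92 in ROSI and 6.45 in TBT. DAAM2, a formin of the actin cytoskeleton, rose from 6.58 to 11.2, and APOB, the structural protein of low-density lipoprotein, from 2.67 to 6.27. PARD3, a cell polarity scaffold (chromosome 10, 34109561 to 34815296), fell from 26.1 ± 1.93 to 19.5 ± 2.54.

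Of 15529 genes, 2543 were called, 1510 higher and 1033 lower (59.4% higher), and 2001 had the same sign in every compound. Of 31083 regions, 5669 were called, 2931 higher and 2738 lower, and 2376 had the same sign in every compound. Among the largest gains were also TNS3 (3.65), PTGES, a prostaglandin E synthase (3.55), SYN3 (3.48), PLXNA4 (3.18), PSMG3 (2.99), TRABD2B (2.98) and CAMTA1 (2.93), with exact permutation tests and Benjamini-Hochberg adjusted p from 0.00127 to 0.010025. The largest losses were at GPR176 (−4.38), JAZF1 (−4.07), LDB2 (−4.02), CDH13 (−3.95), SEMA3A (−3.93), ASAP1 (−3.75), LIPA, the lysosomal acid lipase (−3.64), DST (−3.63) and GALNT5 (−3.47).

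There were 7 lists called, all higher. Glucocorticoid and cAMP targets rose by 12.2 ± 1.60 peaks (SE; exact permutation test, Benjamini-Hochberg adjusted p = 0.000337), with 5 higher (among them MAOA and TSC22D3), 1 lower (PDE4B) and 15 not called (7 and 1 when adjusted over the list alone). Insulin and IGF signalling rose by 8.83 ± 0.948 (exact permutation test, Benjamini-Hochberg adjusted p = 0.000168; 5 higher, 1 lower, 16 not called), with FOXO1 and IGFBP2 higher and TBC1D4 lower. PPAR and RXR partner receptor targets rose by 9.03 ± 1.22 (5 higher, 2 lower, 20 not called; 13 and 4 when adjusted over the list alone), with CRABP2, a retinoic acid carrier, at 8.0 against 5.92 and NR1H3, the LXR-alpha gene, at 3.82 against 5.92. Endothelial markers rose by 7.3 ± 1.29 (4 higher, among them CDH5 and KDR, 0 lower, 9 not called), thermogenic genes by 4.82 ± 0.846 (PPARA, PRDM16 and ESRRA higher, 16 not called), NRF2 targets by 4.59 ± 0.981 (4 higher, among them TXNRD1, GCLC and EPHX1, 19 not called) and muscle markers by 2.95 ± 0.973 with none of 6 members called (MYOG 0.878). In ROSI, PPAR targets (137.5 to 136.3), thermogenic genes (71.0 to 69.7) and NRF2 targets (112.5 to 110.3) did not rise, and the PPAR targets went from 128.0 to 152.3 in TBT and from 126.0 to 130.0 in DMSO. The muscle call was lost in 4 of the 6 other settings (top 30000 peaks, block, 10 kb, each peak counted once) and the endothelial call in 2, while the glucocorticoid and insulin calls held in all 6. Endothelial markers (99.9), glucocorticoid targets (99.6) and insulin genes (98.005) lay above the central 95% of random lists, and the other 4 at percentiles from 82.4 to 95.1. CEBPA, which acts with PPARG in fat cell differentiation, rose from 0.917 ± 0.289 to 2.18 ± 0.874 peaks, in all 3 compounds. PPARG (−0.422), ADIPOQ (−0.339), PLIN1 (1.25), CD36 (−0.139), UCP1 (0.333), RUNX2 (−0.156) and ACTA2 (−0.328) were not called. A region in VPS13D (chromosome 1, 12456735 to 12457235) and another in TNRC18 had a peak in 11 of 11 day 14 and 0 of 12 day 3 libraries, and regions in S100A11 and IGFBP7 had the reverse (exact permutation test, Benjamini-Hochberg adjusted p = 0.00143).

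The remaining lists differed by 7.88 (adipogenic transcription factors), −1.16 (lipid storage), −3.08 (inhibitors of adipogenesis), 0.167 (actin), −1.11 (microtubules), 0.906 (SRF and YAP/TEAD), −5.34 (extracellular matrix), −6.52 (TGF-beta), 2.82 (stem cell surface), −0.25 (osteogenic), 0.0722 (chondrogenic), 0.0611 (blood), −2.55 (epithelial), 1.44 (neural), −7.99 (metal), 5.77 (heat shock), −2.6 (cell cycle), −3.79 (inflammatory) and 3.1 (housekeeping). With all deposited peaks, which are more numerous at day 14, 11114 genes were higher and 281 lower (97.5% higher), and of the losses near named genes only that of NR1H3 stayed called in the same direction. With the top 10000 peaks 153 were higher and 168 lower (47.7% higher), and the glucocorticoid (−0.317), insulin (−1.02), endothelial (−1.68) and muscle lists (−0.689) were not called and had the opposite sign. With a replicate block the exact permutation test called 0 regions and 0 genes (3310 and 2656 at an unadjusted p under 0.05, smallest p 0.00195), so none of the 38 named genes called kept its call. Leaving out any 1 of the 9 TBT libraries lowered the called regions to between 2813 and 3003. PPARG, CD36 and RUNX2 were not called in the shortened lists but were called higher with all deposited peaks. Their differences there were 2.55, 2.59 and 2.59 (exact permutation test, Benjamini-Hochberg adjusted p = 0.0167, 0.00573 and 0.0031).

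The comparison of TBT with DMSO addressed the effect of the organotin at matched days. Peaks near genes of the lipid storage, actin, extracellular matrix, inflammatory and metal response lists rose with TBT. PLIN4 and PLIN5, which encode lipid droplet coat proteins and lie side by side on chromosome 19 (4502192 to 4518486 and 4522531 to 4535224), had 3.59 ± 0.507 and 2.53 ± 0.515 peaks with TBT (SD, n = 17) against 1.47 ± 0.640 and 0.4 ± 0.507 with DMSO (n = 15). SCD, the stearoyl-CoA desaturase (chromosome 10, 100347233 to 100364826), rose from 2.47 ± 0.640 to 4.94 ± 0.827. RSPO1, an enhancer of WNT signalling (chromosome 1, 37611350 to 37634892), fell from 5.33 ± 1.68 to 1.47 ± 0.80, and APOD, a lipid-binding apolipoprotein, from 4.6 ± 1.30 to 1.0 ± 1.32. All 5 genes had these directions at each of the 4 days.

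Of 15707 genes, 4432 were called, 2212 higher and 2220 lower (49.9% higher), and 2965 had the same sign at all 4 days. Of 33957 regions, 8457 were called, 4375 higher and 4082 lower, and 4102 had the same sign at all 4 days. The largest gains were at CPQ (4.29), ZNF469 (4.20), MATN2 (4.15), ZMIZ1 (4.06), STOML1 (3.69), CNIH3 (3.51), NSMCE2 (3.50), COL6A3 (3.45), NAV2 (3.45) and TGM2, the tissue transglutaminase (3.43), with exact permutation tests and Benjamini-Hochberg adjusted p from 1.43e-05 to 0.00144. Beside RSPO1 and APOD, the largest losses were at AKAP13 (−3.90), ANXA8 (−3.63), MED12L (−3.43), ADAMTS9 (−3.15), MYO1D (−3.14), PDE1A (−3.08), ASTN2 (−3.07) and GREB1L (−3.04).

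The lipid storage list rose by 10.04 ± 2.02 peaks (SE), with 8 members higher, 4 lower and 20 not called (8 and 4 when adjusted over the list alone). PLIN2, PNPLA2 and GPAM were also higher, and FASN, LPIN1, GPD1 and ME1 were lower. PPAR and RXR partner receptor targets rose by 9.0 ± 0.964 (6 higher, 2 lower, 18 not called; 6 and 3 when adjusted over the list alone). ABCG1, a cholesterol exporter under LXR control, had 3.41 against 1.6 peaks and TGM2 6.94 against 3.47, while RARB and ABCA1 were lower. The list of adipogenic transcription factors rose by 4.07 ± 1.23 (5 higher, 1 lower, 18 not called), with CEBPB and CEBPD higher and KLF15 lower, but this call was lost in 4 of the 6 other settings (top 30000 peaks, block, each peak counted once, a library left out) and stood at percentile 70.1 of random lists. PPARG (6.41 against 6.8), CEBPA, ADIPOQ, PLIN1, LPL, CD36 and RUNX2 were not called, and ACTA2, the smooth muscle actin, fell from 7.13 to 6.0. Thermogenic genes rose by 3.03 ± 0.656 (3 higher, 3 lower, 12 not called), with KCNK3 higher and PPARGC1A, the PGC-1-alpha gene, lower. The thermogenic call was lost with the top 30000 peaks.

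Actin cytoskeleton and focal adhesion genes rose by 16.2 ± 2.11 (11 higher, 5 lower, 31 not called, the same counts when adjusted over the list alone). TAGLN2, an actin-binding protein, had 5.53 ± 0.717 against 2.87 ± 0.640 peaks. LIMK1, the kinase that phosphorylates cofilin, had 8.0 ± 0.354 against 5.47 ± 0.516, and its window includes ELN. DIAPH3, a formin, was lower. Extracellular matrix genes rose by 14.1 ± 2.39 (10 higher, 3 lower, 20 not called; 10 and 5 when adjusted over the list alone). LOXL1, which cross-links elastin, had 11.2 ± 0.951 against 7.87 ± 0.99 and shares windows with STOML1. TNC, COL1A1 and FBN1 were also higher, and COL3A1 and DCN were lower. TGF-beta signalling rose by 9.58 ± 1.83 (8 higher, among them SMAD3, SMAD7 and ID1, 1 lower, 15 not called) and SRF and YAP/TEAD targets by 6.76 ± 1.61 (9 higher, 3 lower, 15 not called), with FOSL1 higher and CAVIN2 and FOS lower. Microtubule genes fell by 7.33 ± 1.57 (4 lower, among them MACF1, TUBB4B and MAP1B, 1 higher, 26 not called).

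Metal binding and metal response genes rose by 12.1 ± 2.29 peaks, with 9 higher, 1 lower and 5 not called (the same when adjusted over the list alone). The 9 were FTH1, the ferritin heavy chain, SLC30A1, a zinc exporter, and 7 metallothioneins of 1 cluster on chromosome 16 whose windows overlap. MTF1, the metal-responsive transcription factor, was lower. Counted once per peak, the list gained 4.26 peaks (exact permutation p = 0.000644, two-sided). Inflammatory and NF-kB targets rose by 6.97 ± 1.08 (12 higher, 2 lower, 11 not called; 13 and 3 when adjusted over the list alone), with the chemokine genes CCL7 (6.12 ± 0.60 against 3.8 ± 0.775) and CXCL8 (6.47 against 5.13) higher and BIRC3 and IL6 lower. NRF2 targets rose by 5.95 ± 0.885 (5 higher, among them TALDO1 and NFE2L2, 3 lower, among them CAT, 15 not called). Cell cycle genes rose by 5.51 ± 1.23 (6 higher, 3 lower, 20 not called), with the inhibitors CDKN1A and CDKN1C higher and CCND1 lower. Smaller gains were those of epithelial markers (3.2 ± 0.949, with KRT8 and TP63 higher and EPCAM lower) and housekeeping genes (2.61 ± 0.671, with YWHAZ and POLR2A higher). Chondrogenic genes fell by 2.97 ± 0.742 (ACAN and COL9A1 lower, SOX5 higher) and neural markers by 2.06 ± 0.639 (GFAP and RBFOX3 lower, SYP higher), a call lost in 4 of the 6 other settings (top 30000 peaks, block, both window sizes). These 17 lists had Benjamini-Hochberg adjusted p from 1.02e-05 to 0.0278 in exact permutation tests. In all 6 other settings 5 calls held (lipid storage, actin, extracellular matrix, TGF-beta, metal), and that of epithelial markers was lost in 3. Lists outside the central 95% of random lists were lipid storage (99.3), PPAR targets (97.9), inflammatory targets (98.9) and metal response (100), but with each peak counted once and 1 random gene per separate locus the metal list stood at 97.0, inside it. Actin (97.4) and extracellular matrix genes (97.1) lay inside it too, as did SRF and YAP/TEAD targets (84.9), housekeeping genes (83.6) and neural markers (21.4). Only the metal list was compared by separate loci, so percentiles of lists with neighbours such as PLIN4 and PLIN5 may be too extreme. Those not called were inhibitors of adipogenesis (1.23), stem cell surface markers (1.91), osteogenic genes (−0.875), muscle (−0.796), endothelial (−1.50) and blood markers (0.642), heat shock (2.84), glucocorticoid (1.99) and insulin and IGF genes (−1.89).

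By day, the difference in peaks near metal response genes between TBT and DMSO was −0.267, 2.25, 15.8 and 30.8 at days 3, 7, 10 and 14. For PPAR and RXR partner receptor targets it was 2.0, −0.25, 12 and 22.3, and for lipid storage 8.4, −3.25, 11.5 and 23.5. Actin genes gained 17.7, 6.25, 13.3 and 27.8 peaks. At day 14 the metal list held 87.0 ± 5.29 peaks with TBT (SD, n = 4), 56.3 ± 7.5 with DMSO (n = 4) and 51.3 ± 5.03 with ROSI (n = 3). At day 3 the means were 71.4, 71.7 and 75.5, so the list rose with TBT and fell with DMSO and ROSI. These sums count a peak once for each list gene near it, so peaks of the metallothionein cluster enter several times. Values with each peak counted once were not computed by day. None of 312 tests at single days passed Benjamini-Hochberg adjustment in exact permutation tests (88 had an unadjusted p under 0.05, the smallest being 0.00794; no other tool was run). Regions with a peak in all libraries of a compound and none of the other numbered 3171, 2564, 2572 and 5070 at days 3, 7, 10 and 14, where the highest of the other splits gave 570, 254, 187 and 86. A region 65380 bp from ABCA1 (chromosome 9, 104993535 to 104994035) and one in ATOSB had a peak in 17 of 17 TBT and 0 of 15 DMSO libraries. Regions in GRAPL and MOB3B and 65870 bp from DRD2 had the reverse (exact permutation test, Benjamini-Hochberg adjusted p = 1.27e-05).

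**Figure D2:**
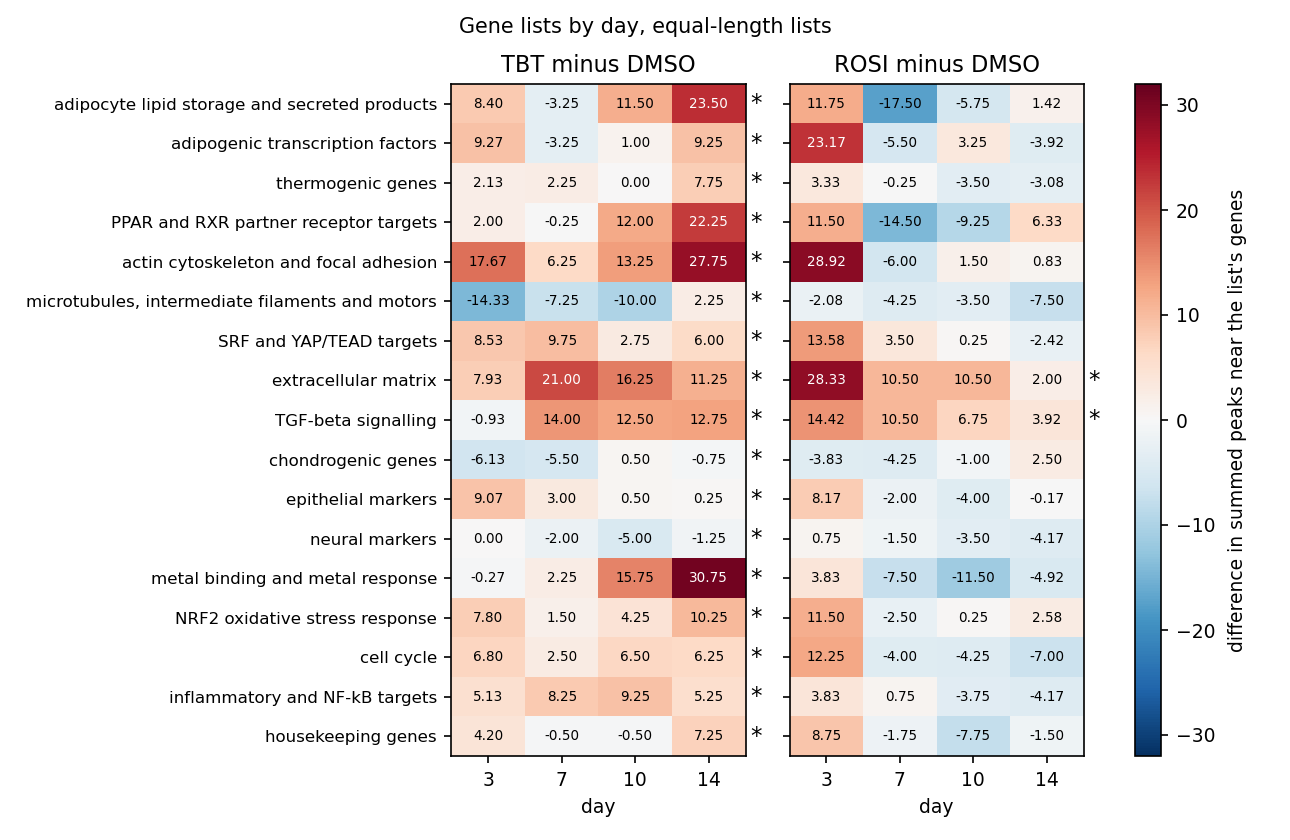
Difference in summed peaks near the genes of 17 lists, TBT minus DMSO and ROSI minus DMSO, at days 3, 7, 10 and 14 (colour and printed values, in peaks); an asterisk marks a list called over the 4 days. With TBT the metal list goes from −0.27 at day 3 to 30.75 at day 14. A peak near several genes of a list is counted for each of them.

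**Figure D3:**
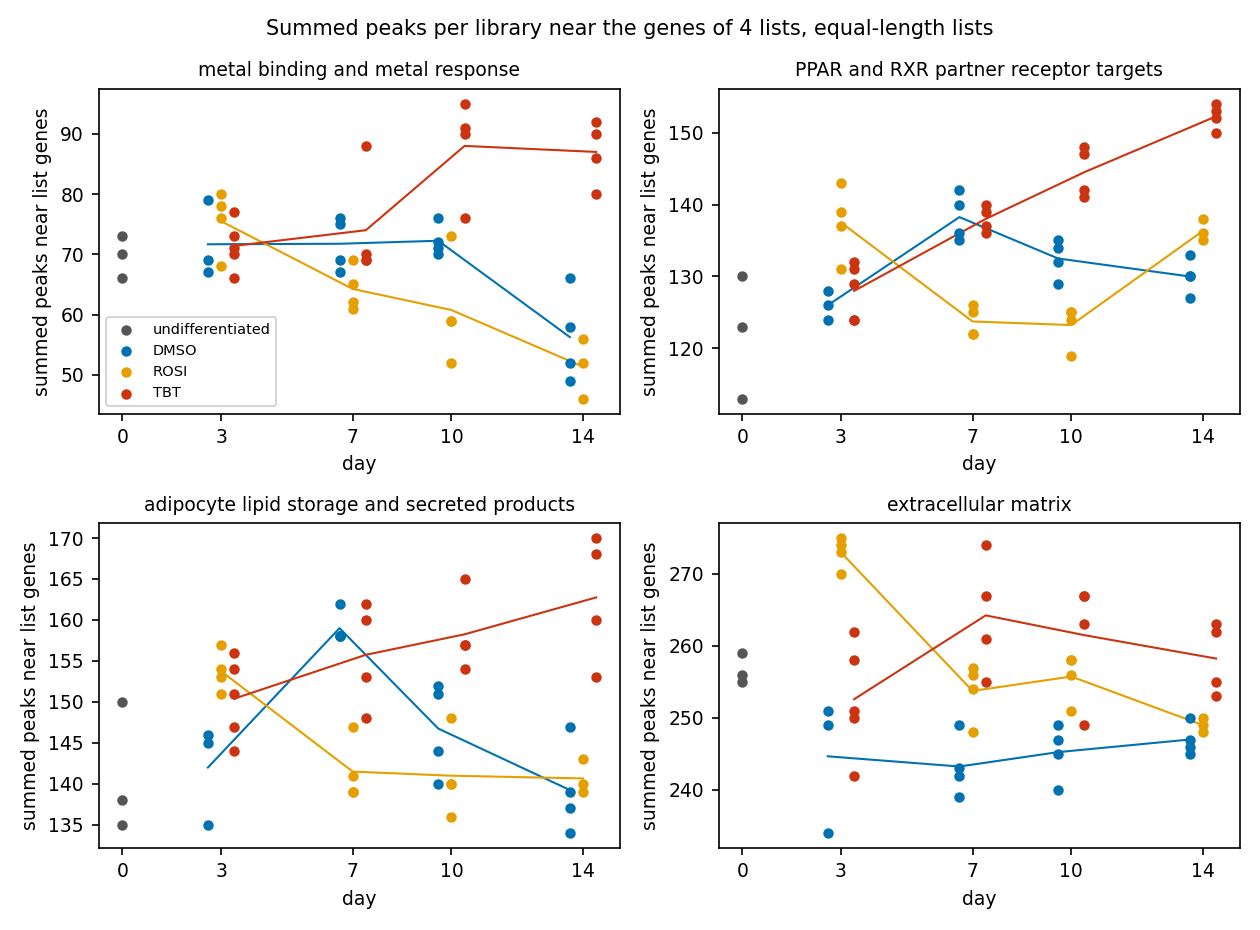
Summed peaks near the genes of 4 lists (vertical axes, which do not start at 0) against the day (horizontal axes); dots are libraries and lines join group means. At day 14 the metal list averages 87.0 peaks with TBT, 56.3 with DMSO and 51.3 with ROSI. A peak near several genes of a list is counted for each of them.

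With all deposited peaks 2904 genes were higher and 4487 lower (39.3% higher), CPQ, ASTN2, MAP1B, CAVIN2, KRT8, EPCAM, MTF1, CDKN1A and ACTA2 changed sign, and the exact permutation test called 0 of 26 lists (6 at an unadjusted p under 0.05; no other tool was run on lists). With the top 10000 peaks 8 lists were called, and the lipid storage, PPAR and extracellular matrix lists were those called higher there; metal response (−0.583), TGF-beta (−2.31), inflammatory (−1.15), SRF targets (−2.51), adipogenic transcription factors (−4.68), thermogenic (−1.82), epithelial (−0.638) and cell cycle genes (−3.06) had the opposite sign. Of these, TGF-beta, adipogenic transcription factors, thermogenic and cell cycle genes were called lower there. PPARG and CD36 were not called in the shortened lists but were called higher with all deposited peaks. Their differences there were 1.80 and 1.75 (exact permutation test, Benjamini-Hochberg adjusted p = 0.00644 and 0.00619). With a replicate block 3467 regions and 2803 genes were called. NFE2L2 and CAT changed sign with 100 kb windows and MTF1 with 10 kb windows.

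Rosiglitazone was compared with DMSO in the same way (15 libraries each), which addressed how an activator of PPAR-gamma changed differentiation. Peaks near extracellular matrix and TGF-beta genes rose, and gains near single genes were largest at day 3 for most of those named. ATXN1 (chromosome 6, 16299112 to 16761460) rose from 13.5 ± 1.60 (SD) to 17.1 ± 2.33 peaks and EBF1, a fat cell transcription factor, from 18.7 ± 1.54 to 21.5 ± 2.13. UCP1 rose from 1.0 in every DMSO library to 1.73 ± 0.594 and CD36, the fatty acid transporter, from 3.2 ± 0.414 to 4.0 ± 0.756, each at 3 of the 4 days. PNOC, the prepronociceptin gene (chromosome 8, 28316988 to 28343351), fell from 5.33 ± 0.816 to 3.2 ± 0.561.

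Of 15624 genes, 1595 were called, 675 higher and 920 lower (42.3% higher), 1032 with the same sign at all days. Of 30788 regions, 2194 were called, 1263 higher and 931 lower, 877 with the same sign at all days. The other large gains were at ASAP1 (3.19), JAZF1 (3.15), TG (2.81), DYM (2.56), PLCB1 (2.56), BNC2 (2.50), PARD3 (2.48) and ARHGAP26 (2.46), with Benjamini-Hochberg adjusted p from 0.00230 to 0.0276 in exact permutation tests. The other large losses were at KIF6 (−2.42), PROK1 (−2.19), MTMR12 (−1.92), PCDHGA6 (−1.83), RNF220 (−1.83), PLEKHA7 (−1.79), LAMA3 (−1.77), ITGAD (−1.75) and WLS, which carries WNT proteins to the cell surface (−1.73).

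Only 2 of 26 lists were called. Extracellular matrix genes rose by 12.8 ± 1.70 peaks (SE), by 28.3, 10.5, 10.5 and 2.0 at days 3, 7, 10 and 14, with MMP2 and COL6A3 higher, 0 lower and 31 not called (COL4A1 1.67). TGF-beta signalling rose by 8.90 ± 1.19, by 14.4, 10.5, 6.75 and 3.92, with 5 higher, among them SMAD6 (9.73 against 7.33), SMAD3 and SKIL, 0 lower and 19 not called (6 higher and 1 lower when adjusted over the list alone). Both had a Benjamini-Hochberg adjusted exact permutation p of 5.85e-05, held in all 6 other settings and stood at percentiles 99.4 and 98.9 of random lists. The lipid storage list (−2.52), PPAR and RXR partner receptor targets (−1.48), adipogenic transcription factors (4.25) and thermogenic genes (−0.875) were not called. For PPAR targets the 95% interval of the average difference was −3.53 to 0.569, which hides opposite signs by day (11.5, −14.5, −9.25 and 6.33 at days 3, 7, 10 and 14). At day 3 adipogenic transcription factors differed by 23.2 and at day 7 by −5.5. Other lists differed by 3.44 (inhibitors of adipogenesis), 6.31 (actin), −4.33 (microtubules), 3.73 (SRF and YAP/TEAD), 0 (stem cell surface), 2.06 (osteogenic), −1.65 (chondrogenic), −2.06 (muscle), −0.688 (endothelial), −2.10 (blood and neural), 0.5 (epithelial), −5.02 (metal), 2.96 (NRF2), −2.69 (heat shock), −0.75 (cell cycle), −0.833 (inflammatory), 1.58 (glucocorticoid), 2.65 (insulin and IGF) and −0.563 (housekeeping), and none was called. PPARG (6.87 against 6.8), CEBPA, ADIPOQ, PLIN1, LPL, RUNX2 and ACTA2 were not called.

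Regions in TRAF3IP2 (chromosome 6, 111604260 to 111604760) and in the overlap of MCFD2 and TTC7A had a peak in 15 of 15 ROSI and 0 of 15 DMSO libraries. Regions in LPXN and 7083 bp from CCDC136 had the reverse (exact permutation test, Benjamini-Hochberg adjusted p = 0.000733). Complete differences by day numbered 5410, 2078, 919 and 1233 regions, where the highest of the other splits gave 662, 165, 389 and 328. The count of day 10 was 1523 without ROSI day 10 replicate 1, and that of day 14 was 1946 without ROSI day 14 replicate 1. With a replicate block the exact permutation test called 0 regions and 0 genes (3786 and 2793 at an unadjusted p under 0.05, smallest p 0.000122), so none of the 27 named genes called kept its call. Without day 3, 791 genes, 1079 regions and 13 lists were called, 10 of the lists lower. With DMSO day 10 replicate 2 left out, 4 lists were called. With all deposited peaks the exact permutation test called 0 lists (1 at an unadjusted p under 0.05), and PROK1, PLEKHA7 and COL6A3 changed sign. CD36 (−0.229) and COL6A3 did so with 10 kb windows, where 406 genes were higher and 366 lower (52.6% higher). With the top 10000 peaks the TGF-beta list differed by −0.0417 and was not called. LPL was not called in the shortened lists but was called higher with all deposited peaks. Its difference there was 0.50 (exact permutation test, Benjamini-Hochberg adjusted p = 0.00491).

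TBT was then compared with ROSI, compounds that both bind PPAR-gamma and whose doses are not given. Peaks near genes of the metal response, lipid storage, PPAR target and inflammatory lists were higher with TBT on average over the days, and those near insulin and IGF genes were lower. ANTXR1, an anthrax toxin receptor (chromosome 2, 69013144 to 69249327), had 22.6 ± 1.62 peaks with TBT (SD, n = 17) and 18.4 ± 1.45 with ROSI (n = 15). NCALD, a neuronal calcium sensor (chromosome 8, 101686542 to 102124907), had 5.12 ± 0.993 against 9.67 ± 1.11, and EBF1 16.9 ± 2.68 against 21.5 ± 2.13.

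Of 15651 genes, 3943 were called, 2132 higher and 1811 lower (54.1% higher), 2484 with the same sign at all days. Of 34316 regions, 8569 were called, 3997 higher and 4572 lower, 3187 with the same sign at all days. The largest gains included NAV2 (4.10), ZNF469 (3.55), CFAP45 (3.45), HIVEP3 (3.28), CPQ (3.23), MATN2 (3.17), PEBP4 (3.01), CAST (2.97) and TGM2 (2.86), with Benjamini-Hochberg adjusted p from 2.68e-05 to 0.00381 in exact permutation tests. The other large losses were at MYO1D (−4.35), RSPO1 (−4.09), PARD3B (−4.09), PLCB1 (−4.04), FBXL7 (−3.79), EXT1 (−3.79), UST (−3.73) and SLIT2, an axon guidance ligand (−3.71).

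The metal list was higher by 17.1 ± 2.34 peaks (SE; 8 members higher, among them SLC30A1 and MT1E, 1 lower, 6 not called; 10 and 2 when adjusted over the list alone). With each peak counted once it was higher by 5.11 peaks (exact permutation p = 0.000207, two-sided). At day 3 the metal (−4.1), lipid storage (−3.35), PPAR target (−9.5) and actin lists (−11.3) differed the other way, and at days 7, 10 and 14 all 4 were higher with TBT. Lipid storage was higher by 12.6 ± 1.75 (9 higher, 1 lower, 22 not called), with SCD, PLIN4 and PLIN5 higher and CD36 lower. PPAR and RXR partner receptor targets were higher by 10.5 ± 1.05 (11 higher, 2 lower, 13 not called), with ABCA1, the cholesterol efflux transporter, lower (7.82 against 10.2). Actin genes were higher by 9.92 ± 1.68 (16 higher, among them TAGLN2, TLN1 and TPM2, 8 lower, 23 not called) and inflammatory targets by 7.80 ± 1.07 (9 higher, among them CCL7, CCL8 and CCL20, 1 lower, 15 not called). Cell cycle genes (6.26 ± 1.42, with PCNA, CDKN1A and CDKN1C), heat shock and unfolded protein genes (5.53 ± 1.37, with DDIT4 and HSPA5 higher and ASNS lower), thermogenic genes (3.91 ± 0.611, with PPARGC1B and KCNK3 higher and UCP1 lower), blood cell markers (2.75 ± 0.60, with CD4 and PTPRC higher and CD3D lower) and epithelial markers (2.70 ± 0.813, with KRT14 and KRT19 higher and GRHL2 lower) were also higher. Insulin and IGF signalling fell by 4.54 ± 0.848 (0 higher, 4 lower, among them IGF1 and IGF1R, 18 not called) and osteogenic genes by 2.94 ± 1.08 (BGLAP and PHEX lower, DLX3 higher), a call kept in 0 of the 6 other settings. The 12 lists had Benjamini-Hochberg adjusted p from 0.000146 to 0.0466 in exact permutation tests. In all 6 other settings 4 calls held (metal, lipid storage, thermogenic, blood), that of epithelial markers was lost in 3, and that of actin genes was lost with the block and with each peak counted once. The inflammatory call was lost with the top 30000 peaks and with 10 kb. The insulin call was lost with the top 30000 peaks, and the PPAR target call with 10 kb. The metal (100, or 97.9 by separate loci), lipid storage (99.8), PPAR (98.8) and inflammatory lists (97.9) lay outside the central 95% of random lists, and the other 8 at percentiles from 4.87 to 89.8. Only the metal list was compared by separate loci, so other lists with neighbouring genes may stand too far out. ACTA2 was lower (6.0 against 7.4), and PPARG, CEBPA, ADIPOQ, PLIN1, LPL and RUNX2 were not called.

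Lists not called between TBT and ROSI included extracellular matrix (1.28, 95% interval −2.56 to 5.11) and TGF-beta signalling (0.683, −2.97 to 4.34), the 2 lists that rose with both compounds. These averages join unlike days: extracellular matrix differed by −20.4 at day 3 and by 10.5, 5.75 and 9.25 later, and TGF-beta signalling by −15.35 and then 3.5, 5.75 and 8.83. The others were adipogenic transcription factors (−0.183), inhibitors of adipogenesis (−2.21), microtubules (−3.0), SRF and YAP/TEAD (3.03), stem cell surface (1.91), chondrogenic (−1.33), muscle (1.27), endothelial (−0.808), neural (0.0417), NRF2 (2.99), glucocorticoid (0.404) and housekeeping genes (3.18). The ATOSB region and regions in SBDS and LPXN had a peak in 17 of 17 TBT and 0 of 15 ROSI libraries, and regions in ARNT2, ELMOD3 and RPLP0 had the reverse (exact permutation test, Benjamini-Hochberg adjusted p = 2.15e-05). Complete differences by day numbered 2227, 2841, 3187 and 5497 regions, with 443, 116, 327 and 760 as the highest of the other splits. From all deposited peaks, 2610 genes were higher and 3936 lower (39.9% higher), none of the 12 lists stayed called (the 1 list called was muscle, −4.62), and HIVEP3, CPQ, PPARGC1B, PHEX and CD36 changed sign. The osteogenic list had the opposite sign with 100 kb windows (2.94), and so had the thermogenic (−1.28), epithelial (−0.763) and cell cycle lists (−1.81) with the top 10000 peaks. Of the 12 only lipid storage (6.45) and PPAR targets (6.38) were called there, and metal response (2.125) and inflammatory targets (0.104) were not. LPL was not called in the shortened lists but was called lower with all deposited peaks. Its difference there was −0.60 (exact permutation test, Benjamini-Hochberg adjusted p = 0.00145).

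Genes called in both TBT and ROSI against DMSO numbered 285 higher in both, 386 lower in both and 43 with opposite directions, of 15327 genes tested in both. Independent lists of these sizes would share 92.1 and 132 genes, but the calls share their DMSO libraries. Simulated unchanged groups had 0 calls for either compound, so they give no value for the shared counts. Over genes, which are not independent replicates, the differences correlated with r = 0.423 and a covariance of 0.152, where unchanged groups gave a median r of 0.503 and a median covariance of 0.0265 (0.0101 to 0.0606). Each simulated library drew its noise separately, with none shared by a group. The simulation therefore cannot show how far noise shared by the DMSO libraries of a day raises the covariance. At days 7, 10 and 14 the shared DMSO libraries gave 199 genes in the same direction with a covariance of 0.111. With the DMSO libraries split between the compounds, the median covariance was 0.0741 and the exact permutation test called 0 genes for ROSI, so 0 genes could be shared. The split libraries come from the same DMSO groups and keep any noise that a group shares. A shared response to the compounds can therefore not be concluded from these values.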

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

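The tests of list length and of gains near all peak-rich genes were chosen after the results were seen. Among groups of 4 or 5 libraries, 4 values of 30 stood far from the rest of their group, where chance gives about 1.5. TBT day 3 replicate 3 had 36742 peaks, DMSO day 10 replicate 2 had 65401, and TBT day 14 replicate 1 had 64961 peaks covering 30.03 Mb. These libraries were kept.

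The difference between TBT and DMSO changed from day 3 to day 14 for 8 lists, and that between ROSI and DMSO for 2, of 19 tested (permutation test on the residuals of a fit with compound and day but no interaction, two-sided, 10000 resamples, Benjamini-Hochberg adjusted). The difference in the metal list between TBT and DMSO grew by 31.0 peaks, through a rise with TBT and a fall with DMSO, with the smallest possible permutation p of 1e-04 (adjusted p = 0.00095), and that in PPAR and RXR partner receptor targets by 20.25 (0.00095). It rose by 16.6 for microtubules (0.0129), 15.1 for lipid storage (0.0465), 13.7 for TGF-beta signalling (0.0152), 5.62 for thermogenic (0.0152) and 5.38 for chondrogenic genes (0.0195), and moved by −8.82 for epithelial markers (0.00617). The difference between ROSI and DMSO moved by −26.3 for the extracellular matrix (0.00253) and by −10.5 for TGF-beta signalling (0.0458). All these values count a peak once for each list gene near it. Peaks of the metallothionein cluster thus enter the metal value several times.

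Libraries of a group were more alike than libraries of different compounds at all 4 days. A filter applied to each group as a whole could make them so. Among the top 10000 peaks the within-minus-between Jaccard index was at least 0.062046, and over regions with a peak in every library of a day the rank correlations were higher within groups (highest exact permutation p 0.00051948, one-sided), both against the filter as the whole cause. Unequal list length is argued against by a difference of at least 0.084223 in lists of equal length. Separate handling of each group's dishes stays open, and an effect of the compound is a hypothesis.

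Differences between TBT and DMSO pointed the same way at 4 days for 3633 genes, against at most 1451 in the other 7 ways to swap whole groups. This argues against separate noise of each group's filter. List length differed by 8095.2 peaks at day 3 and with the opposite sign at later days, which argues against it as the cause of a shared direction. With 1 value per group the smallest exact p is 0.125, so a lasting effect of TBT stays a hypothesis.

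Metal response genes gained peaks with TBT, 7 of them in 1 cluster. Counting each peak once cut the difference from 12.1 to 4.26 peaks (exact permutation p = 0.00064431), so repeated counting explains much of its size but not all of it. For the difference of 12.1, leaving out any 1 library gave at most p = 0.001698 (exact permutation test, two-sided), which argues against a single library. The once-counted difference was not tested with a library left out. The once-counted difference stood at percentile 96.98 of 10000 random lists with 1 gene of like mean count for each of the 10 separate loci. That lies inside the central 95%, so this comparison does not decide. The random lists had a median difference of 0.0917 peaks, which argues against a gain of 4.26 near genes of like count in general. That 10 loci drawn at random differ as much stays open. Counted per gene, the difference was −0.583 with the top 10000 peaks, so the gain of 12.1 lies among lower-ranked peaks. An effect of the tin compound on these genes is a hypothesis, and metal levels were not measured.

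Other splits of the libraries within their days or compounds, 100 for each result with the real one, tested chance. With 1 value per group, no exact p falls below 0.125 in the compound comparisons. Day 0 and day 14 against day 3, with fewer groups, could not reach even that. For day 0 the DMSO libraries of all 4 days also form 1 pool. The splits shuffle libraries as if independent, so they address chance among libraries and not noise shared by the libraries of a group. If a group shares a filtered set of peaks, the real split would stand out without any effect of compound or day. Chance between groups can therefore not be excluded by them. Only if libraries are independent do the counts of regions and genes argue against chance. The real region counts were 12254, 5669, 8457, 2194 and 8569 and the gene counts 4760, 2543, 4432, 1595 and 3943 for day 0, day 14 against day 3, TBT and ROSI against DMSO, and TBT against ROSI, and in each case only 1 split, the real one, reached it, with 0 as the highest of the others. Since adjustment can keep a split at 0, most of all for day 0 with its smallest p of 0.00123, counts at an unadjusted p under 0.05 were added after the results were seen. For day 0 the real counts were 14992 regions and 6587 genes, against at most 1472 and 2340 in the other splits, and only the real split reached them in the other comparisons too. Under the same condition the list counts argue against chance, with 15 against a highest of 6, 7 against 5, 17 against 4 and 12 against 5. These are for day 0, day 14 against day 3, TBT against DMSO and TBT against ROSI. For the 2 lists of ROSI against DMSO, 3 of the 100 splits, the real one included, gave as many, with 2 as the highest of the others. That is under the share of 0.05 set beforehand by a small margin only. Since other splits reached the real count, this count alone does not firmly exclude chance among libraries.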

How the results depend on the processing

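The top 10000 peaks and the setting without day 3 were chosen after seeing the data, and the other alternatives were planned. Of the calls for named genes, 215 had the same direction and side of the threshold with the top 30000 peaks and 35 did not, and so had 232 of 255 with windows of 100 kb, 175 of 207 with 10 kb, 255 of 255 without the minimum mean, 196 of 216 without day 3, 244 of 255 with any 1 library left out, 182 of 255 with the replicate block, 129 of 254 with all deposited peaks, and 30 of 254 with a block on the number in the title. Few permutations remain with the last block. The smallest exact permutation p was 0.0222 for day 0 and 0.0156 for day 14 against day 3, where a loss of the call says little. It was 0.00391 for TBT and 0.00195 for ROSI against DMSO, where 0 of 67 and 0 of 27 calls were kept. There too, adjustment over all tested genes allows a call only if many genes share that smallest p, so these losses weigh little. Of the 53 called lists 41 kept direction and side of the threshold with the top 30000 peaks, 41 with 100 kb, 39 with 10 kb, 38 with the replicate block, 45 with any 1 library left out, 47 with each peak counted once per list, 14 with the top 10000 peaks and 13 with all deposited peaks. The TBT gains of the lipid storage, actin, extracellular matrix, TGF-beta and metal lists stayed called with the top 30000 peaks, both window sizes, each peak counted once and with any 1 library left out, and none of them was called with all deposited peaks. The 18 motif results were not run because no genome sequence was at hand. Read depth is unknown, so its limit on these counts was not measured.

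With all deposited peaks, whose numbers differ between groups, the called regions, genes and lists numbered 45115, 11127 and 24 for DMSO against day 0. They were 37670, 11395 and 26 for day 14 against day 3 and 24826, 7391 and 0 for TBT against DMSO, where the exact permutation test for the lists gave 6 at an unadjusted p under 0.05. For the rest they were 10808, 3350 and 0 for ROSI against DMSO, where 1 list had an unadjusted p under 0.05, and 24570, 6546 and 1 for TBT against ROSI; no other tool was run on lists. Genes called in the same direction for TBT and ROSI numbered 1597. Regions that separated 2 groups completely at days 3, 7, 10 and 14 numbered 7260, 16187, 13439 and 20894 for TBT against DMSO. They numbered 22359, 14444, 11363 and 11631 for ROSI against DMSO and 12689, 16922, 13430 and 21614 for TBT against ROSI. The cause was not tested.

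These differences had the opposite sign with all deposited peaks. DMSO against day 0 gave ZBTB20 −4.07, FBXL7 −2.07, ARHGAP26 −7.67, SLIT3 −3.13, LRMDA −4, PRKG1 −15.3, PTPRG −1.80, RBMS3 −6.73, PARD3 −5.67, EBF1 −14.4 and ZBTB16 −0.733. Further values for day 0 were TCF7L2 −3.93, ELOVL3 −1.47, TGFBR2 −0.733, LTBP2 −1.67, ANPEP −0.267, CD44 −0.600, NT5E −0.600, ACAN −0.533, MATN1 −3.33, GRHL2 −6.40 and TXNRD1 −2.13. More genes of that comparison were NFE2L2 −0.933, FKBP5 −1.27, PIK3CA −0.733, IGF1 −1.40, TBC1D4 −2.93, PPARG −1.67, PLIN1 −0.600, CD36 −0.400 and RUNX2 −0.600. Its lists gave lipid storage −70.7, adipogenic factors −78.9, adipogenesis inhibitors −47.9, PPAR targets −65.7, actin −116, SRF and YAP/TEAD −84.3, TGF-beta −76.1 and stem cell surface −34.7. More of its lists gave osteogenic −73.3, chondrogenic −36.1, NRF2 −46.5, heat shock −56.9, glucocorticoid −43.6, insulin −72.2 and housekeeping −31.7. Day 14 against day 3 gave PARD3 2.08, JAZF1 6.45, LDB2 4.39, CDH13 5.91, SEMA3A 1.961, ASAP1 1.11, LIPA 0.861, DST 2.53, GALNT5 1.33, PDE4B 0.883, TBC1D4 0.172, PPARG 2.55, CD36 2.59 and RUNX2 2.59. Lists in that comparison gave lipid storage 56.8, adipogenesis inhibitors 30.8, microtubules 41.8, extracellular matrix 65.6, TGF-beta 45.2, osteogenic 26.4, epithelial 21.4, metal 12.04, cell cycle 30.02 and inflammatory 20.6. TBT against DMSO gave CPQ −0.642, ASTN2 0.125, MAP1B 0.450, CAVIN2 0.725, KRT8 −0.787, EPCAM 1.82, MTF1 0.350, CDKN1A −0.392, PPARG 1.80, CD36 1.75 and ACTA2 0.375. Its lists, none of them called there, gave thermogenic −0.579, microtubules 5.67 and extracellular matrix −3.27. ROSI against DMSO gave PROK1 0.125, PLEKHA7 1.56, COL6A3 −1.04 and LPL 0.500. TBT against ROSI gave HIVEP3 −0.575, CPQ −0.704, PPARGC1B −0.425, PHEX 0.792, LPL −0.600 and CD36 1.58. The list there was muscle −4.62. For day 0 and for day 14 against day 3, all these values went with list length, which was on average greater at day 0 and at day 14. No test separated list length from other causes of these changes.

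With the top 10000 peaks, chosen after seeing the data, fewer peaks enter each count. Called regions and genes numbered 2686 and 1394 for DMSO against day 0, 512 and 321 for day 14 against day 3, and 1647 and 1476 for TBT against DMSO. They were 505 and 477 for ROSI against DMSO and 1823 and 1171 for TBT against ROSI. Lists called numbered 2 for day 14 against day 3 and 8 for TBT against DMSO. Lists with the opposite sign were, for day 0, PPAR targets −5.40, actin −12.3, extracellular matrix 2.87, endothelial 2.40 and inflammatory 10.3. For day 14 against day 3 they were muscle −0.689, endothelial −1.68, glucocorticoid −0.317 and insulin −1.02. TBT against DMSO had adipogenic factors −4.68, thermogenic −1.82, SRF and YAP/TEAD −2.51, TGF-beta −2.31, epithelial −0.637, metal −0.583, cell cycle −3.06 and inflammatory −1.15. ROSI against DMSO had SRF and YAP/TEAD −5.04 and TGF-beta −0.0417, and TBT against ROSI thermogenic −1.27, TGF-beta −2.27, stem cell surface −2.86, endothelial 2.35, epithelial −0.762 and cell cycle −1.81. The cause was not tested.

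Windows of 10 kb hold fewer peaks per gene, and 2791, 1276, 2399, 772 and 2145 genes were called in the 5 comparisons in the order above. The sign changed for MTF1 (0.138) in TBT against DMSO and for COL6A3 and CD36 (both −0.229) in ROSI against DMSO. With 100 kb, 8 lists were called for day 0 and 6 for ROSI against DMSO, and the actin (−24) and extracellular matrix lists (0.133) of day 0 changed sign. So did the blood list (−4.29) in day 14 against day 3, NFE2L2 (−0.671) and CAT (0.171) in TBT against DMSO, and the osteogenic list (2.94) in TBT against ROSI. With the top 30000 peaks the day 0 inflammatory list gave 5.47, 6 lists were called for ROSI against DMSO, and complete differences at day 3 numbered 1791 for TBT and 3504 for ROSI against DMSO. The cause was not tested.

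With the number in the replicate label as a replicate block, the permutations stay within a number, which leaves fewer of them, and the labels do not pair the samples. Deviations from the group means in libraries with the same number correlated above 0.1 in 6 of 44 pairs (−0.091 to 0.215), and in 6 of 31 pairs for the number in the title. Called genes numbered 3065 for day 0, 2803 for TBT against DMSO and 1939 for TBT against ROSI, and called regions 3467 and 3031 for these 2 compound comparisons. For day 14 against day 3 the exact permutation test called 0 regions and 0 genes (3310 and 2656 at an unadjusted p under 0.05) and 2 lists, and for ROSI against DMSO 0 regions and 0 genes (3786 and 2793). With a block on the number in the title it called 0 genes for day 0, day 14 against day 3, TBT and ROSI against DMSO (5004, 1034, 2559 and 1461 at an unadjusted p under 0.05) and 641 for TBT against ROSI. limma without a block called 6616, 3476, 5205, 2461 and 4566 genes in the 5 comparisons.

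With every variable region tested, 3022 regions were called for day 14 against day 3. limma called 2461 genes for ROSI against DMSO, where the exact permutation test called 1595. Without day 3, which leaves fewer libraries, 1079 regions, 791 genes and 13 lists were called for ROSI against DMSO. With the DMSO libraries of days 7, 10 and 14 split between the compounds, the median overlap of TBT and ROSI calls was 0, since the exact permutation test called 0 genes for ROSI with fewer controls.

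With 1 library left out at a time, day 0 gave 0 to 12827 regions, 2778 to 4930 genes and 10 to 16 lists, and the region count was 0 without any of the 3 day 0 libraries (exact permutation test, smallest p 0.0221, 3325 to 3551 regions at an unadjusted p under 0.05). That 0 says little, because the minimum of 3 libraries with and 3 without a peak then removed every complete difference before testing. Day 14 against day 3 gave 2813 to 5462 regions, 2040 to 2283 genes and 7 to 10 lists, with the region count at most 3003 without any of the TBT libraries. TBT against DMSO gave 8061 to 8760 regions, 4178 to 4534 genes and 16 to 17 lists. ROSI against DMSO gave 1687 to 2243 regions, 1275 to 1761 genes and 2 to 4 lists, with 4 lists without DMSO day 10 replicate 2. TBT against ROSI gave 7622 to 8400 regions, 3578 to 3865 genes and 11 to 14 lists. Complete differences between ROSI and DMSO ranged from 1088 to 1523 at day 10, the latter without ROSI day 10 replicate 1, and from 1537 to 1946 at day 14, the latter without ROSI day 14 replicate 1. Peaks per library differed by −1660 to −409 for TBT against DMSO, by −997 to −59.7 for ROSI against DMSO and by −1167 to 155 for TBT against ROSI, the last without TBT day 3 replicate 3. The within-minus-between difference in Jaccard index stayed between 0.0798 and 0.133 over the 4 days.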

Other observations

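The days and groups named in this paragraph were chosen after their values were seen. PLIN5 had 3.0 peaks in each TBT library of days 7 and 10, and 0 in each ROSI library of days 7, 10 and 14. MT1E, a metallothionein gene, had 6.0 ± 0.816 peaks at day 14 with TBT (SD, n = 4), 2.75 ± 0.957 with DMSO (n = 4) and 1.33 ± 0.577 with ROSI (n = 3). RSPO1 had 2.25 ± 1.26 peaks at day 10 with TBT, 7.0 with each DMSO library and 6.75 on average with ROSI.

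Chromosome Y was left out of the shares that follow. The share of peaks on contigs outside the main chromosomes was 1.25% at day 0 and 1.07% in differentiated DMSO libraries (difference −0.179, exact permutation test, two-sided, Benjamini-Hochberg adjusted p = 0.00613). TBT and DMSO had 1.08% and 1.07% (difference 0.0148, permutation p = 0.0367, Benjamini-Hochberg adjusted p = 0.0917). Genes with the same sign at 4 days numbered 2095 for ROSI against DMSO, with 1567 as the highest of the other ways to swap whole groups, and 3343 for TBT against ROSI, with 2319. Neither count met the margin that had been set beforehand for TBT against DMSO. Separate noise of each group's filter therefore stays open for both comparisons. Across genes, the TBT differences of 2 days correlated with r between 0.267 and 0.530, and the ROSI differences with r between 0.0198 and 0.385.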
